A study of Homo sapiens with 6 samples.

How the data were processed

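RNA sequencing of HCT-8 cells gave 6 libraries, 3 from untreated cells and 3 from cells treated with 5-FU. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit, which as named does not mark strand; whether polyadenylated RNA was selected is not stated there. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 were used with genome build GRCh38; the strand setting and the treatment of reads that fit several genes are not given in the sources used here. The deposited count table holds whole-number counts per gene for 58735 genes, with a gene class and position for each. All 58735 identifiers and positions matched GENCODE release 29. The deposited FPKM table gives FPKM, fragments scaled by gene length and library size, for the same genes. Tested on the values, its FPKM equal the count divided by the gene length and by 1 constant per library. That constant was 0.906, 0.986 and 0.892 times the count total in the control libraries and 1.16, 1.09 and 1.07 times in the 5-FU libraries, so the authors' FPKM values carry a scaling beyond the plain total.

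Total counts ranged from 18459939 to 23495607 per library. Intervals on shares from such totals cover counting error only; the exact 95% binomial interval of the mitochondrial share in control replicate 1, for example, was 4.84% to 4.86%. Pairs of libraries of 1 group differed by 10.5 to 27.7 chi-square units per gene, beyond the 1 expected of counting noise; repeat libraries of a single culture would exceed it too, so this does not show separate cultures.

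Groups were taken from the treatment label. The comparison of 5-FU with control used all 6 libraries and the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with filterByExpr at its defaults (minimum count 10, minimum total 15), TMM factors, a design of group alone and Benjamini-Hochberg adjustment; 19771 genes were tested and an adjusted p under 0.05 was called. CPM are TMM-normalized. The SE of a log2 fold change is the size of the unshrunk coefficient divided by the square root of the F statistic. Gene lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The preset takes members to be nearly independent; with an estimated correlation none of the 19 called lists passed. fry asks whether a list's genes move one way on balance and does not set them against other genes. Comparisons of a single value used an exact two-sided permutation test, which cannot go below 0.1 for 3 against 3.

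The design, the 29 lists and the rule for named genes were fixed before the data were examined. The rule names CD44 and ELF3, then the 12 largest increases and 12 largest decreases among protein-coding genes with an adjusted p under 0.05, a mean count of at least 100 and groups that do not overlap. For each list it names up to 3 members of smallest p among those that passed, or 4 where the list passed camera, or the 2 most abundant where none passed. For markers of other cell types and mitochondrial genes it names the most abundant member. It gave 113 genes, of which 41 share exonic bases with another annotated gene and 1 shares over 50% of them. Of the genes the rule gave, 3 are not reported here, though they count in these totals and in those of their lists. Reads in such stretches cannot be assigned from the tables alone.

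Alternatives fixed beforehand were DESeq2 size factors and upper-quartile factors in edgeR, no low-count filter, a mean count of at least 50, the tests of DESeq2 1.42.0 and limma-voom, the replicate number as a block, leaving out each library, and limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) of genes with FPKM of at least 1 in 3 or more samples, or with no such filter. Fold changes on those log2 scales understate the change of low genes. Chosen after seeing the data were plain library totals, leaving out mitochondrial genes, and removal of a smooth trend on gene length and GC content (span 0.3) from each library, for which 19763 of the 19771 tested genes had a GC value.

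On simulated counts for this comparison (19215 genes, 6 libraries, 200 genes changed), edgeR recovered 90.9% of 4-fold, 61.2% of 2-fold and 11.9% of 1.5-fold changes, with 5 false calls. The simulated changes were few and balanced in direction, whereas 70.2% of tested genes were called in the data. These rates of recovery and false calls therefore do not carry over to the real comparison.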

Results

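RNA was sequenced from HCT-8, a human colorectal adenocarcinoma cell line grown as a monolayer. The labels describe 3 untreated control samples and 3 samples treated with 5-fluorouracil (5-FU), a fluoropyrimidine that blocks thymidylate synthase and is built into RNA and DNA. The drug was used at its 10% inhibitory concentration, a low dose that the labels relate to continuous infusion; the molar concentration and the duration were not given in the sources used here. Gene counts summed to 23495607, 22068865 and 21659252 in the control libraries and to 18813817, 18459939 and 20613228 in the 5-FU libraries. The comparison asks which transcripts differ after low-dose 5-FU, with CD44 and ELF3 as the genes named in the study's title. Nothing in the labels says that the samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

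ELF3, an ETS family transcription factor of epithelial cells, rose 5.52-fold after 5-FU, from 42.9 ± 9.60 to 237 ± 35.4 in normalized counts scaled to library size (CPM; mean ± SD, n = 3 per group). CD44, a hyaluronan receptor and a marker of colorectal tumour cells with stem-like properties, rose 1.35-fold, from 52.1 ± 4.23 to 70.3 ± 9.32 CPM. For both genes each 5-FU library lay above each control library. The log2 fold change was 2.47 (SE 0.18, edgeR adjusted p = 1.24e-06) for ELF3 and 0.43 (SE 0.13, edgeR adjusted p = 0.0108) for CD44, against a median of 0.09 over all tested genes. ELF3 (ENSG00000163435) lies on chromosome 1 at 202007945 to 202017188 and CD44 (ENSG00000026508) on chromosome 11 at 35138870 to 35232402, both on the plus strand of GRCh38. Exons of an antisense gene, ELF3-AS1, cover 9.2% of the exonic bases of ELF3, a sense-intronic gene on its own strand covers 9.2%, and exons of CD44-AS1 cover 0.8% of those of CD44; whether counting used strand is not stated. The CD44 call was lost in DESeq2 (adjusted p = 0.109), without the low-count filter (edgeR adjusted p = 0.111), without control replicate 3 (edgeR adjusted p = 0.0758) and on the FPKM table (limma adjusted p = 0.0791), and its log2 fold change ranged from 0.24 to 0.79 over all settings.

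**Figure D1:**
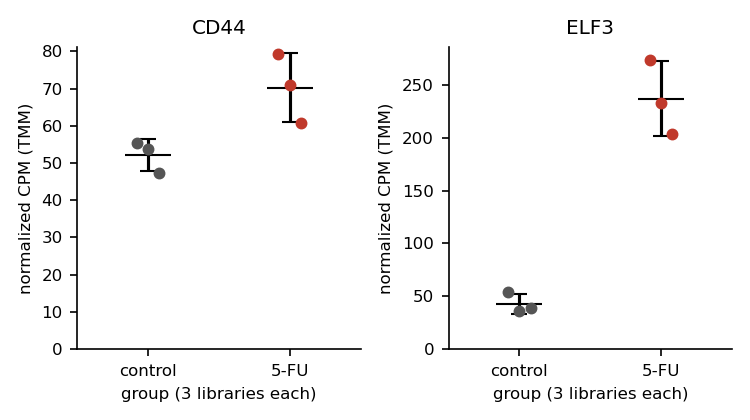
Normalized CPM of CD44 (left) and ELF3 (right) in each library, with 3 control libraries in grey and 3 5-FU libraries in red; bars show the mean and SD. The 5-FU libraries lie between 60.6 and 79.3 CPM for CD44 and between 203 and 274 CPM for ELF3, above the control libraries in both panels.

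Over the transcriptome, 13877 of 19771 tested genes (70.2%) differed between the groups in edgeR's quasi-likelihood test at an adjusted p under 0.05, 7171 of them higher and 6706 lower after 5-FU. At a fold change of at least 2, 5008 genes were higher and 3206 lower. The first principal component carried 85.8% of the variance of log2 CPM and separated the groups. The ranges of the groups did not overlap for 74.3% of genes, where chance gives 10%. The balance of higher and lower genes depends on how libraries are scaled: with upper-quartile factors 9602 genes were higher and 4614 lower, and the median of all genes moved up by 0.36 on the log2 scale. In the FPKM values, whose scaling stays as deposited, the balance depends on which genes are tested as well. There 4320 were higher and 7136 lower among genes with FPKM of at least 1 in 3 samples, against 6926 and 6902 without that filter. In the counts, with TMM factors computed anew after each filter, 5141 were higher and 4935 lower at a mean count of at least 50. Without the low-count filter 8157 were higher and 7588 lower.

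Among protein-coding genes with a mean count of at least 100, the largest increase was that of CCND2, a D-type cyclin (log2 fold change 6.32, SE 0.48). It was followed by CPA4, a carboxypeptidase (6.01, SE 0.42), HSPA6, an inducible heat shock protein (5.65, SE 0.72), AMY2B, an amylase (5.54, SE 0.42), and ANKRD1, a target of the YAP coactivator (5.46, SE 0.56). TAS2R5 (4.74), TRIM22 (4.66), TRIML2 (4.54), MAP2 (4.27), DKK1 (4.27), CSMD3 (4.20) and RASGRP3 (4.11) completed the 12 largest. Control levels of all 12 were low, from 0.29 CPM for CCND2 (counts of 9, 7 and 3) to 2.68 CPM for TRIM22 (92, 45 and 38). They thus reached the mean count mostly through the 5-FU libraries. Levels reached 154 ± 78.9 CPM for CPA4, 113 ± 72.7 CPM for ANKRD1 and 45.4 ± 44.15 CPM for HSPA6, so the spread within the 5-FU group was wide for these genes. For HSPA6 it came mostly from 5-FU replicate 3 (96.1 CPM, against 24.2 and 15.8 in the others), without which its log2 fold change was 4.44 and still passed. Exons of other genes on the same strand cover 32.3% of the exonic bases of AMY2B, whose near-identical amylase paralogs can also share its reads, so its value is uncertain. HSPA6 has a close copy, HSPA7, and is uncertain for the same reason.

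Genes of G2 and mitosis fell furthest. Of 35 members of that list all fell, with a median log2 fold change of -3.72. CCNB1, the cyclin that drives entry into mitosis, dropped from 245 ± 76.2 to 6.88 ± 1.38 CPM (log2 fold change -5.15, SE 0.25), and CDC20, an activator of the anaphase-promoting complex, from 274 ± 111 to 5.87 ± 2.60 CPM (-5.54, SE 0.38). The kinesin KIF20A (-5.25), CCNB2 (-4.11) and the centromeric histone CENPA (-3.43) fell as well. BIRC5 (-5.19), LMNB1 (-4.72), NEK2 (-4.71), HMMR (-4.62), TOP2A (-4.57), AURKA (-4.54), PRR11 (-4.42), UBE2C (-4.40) and RPL22L1 (-4.33), most of them genes of dividing cells, were among the 12 largest decreases. The list passed camera with its preset correlation (adjusted p = 4.59e-33), with adjusted p = 0.36 with an estimated correlation.

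DNA replication genes fell with them: 35 of 37 were lower, at a median of -2.40, among them the helicase subunits MCM2 (-3.21), MCM5 (-3.12) and MCM6 (-3.12) and the primase subunit PRIM1 (-3.13). Exons of genes on the opposite strand cover 23.6% of MCM2. Of 28 tested genes of homologous recombination and crosslink repair 26 fell, at a median of -1.77, including the checkpoint kinase CHEK1 (-2.87), UBE2T (-2.80), H2AFX (-3.26) and RMI2 (-2.57). Both lists passed camera (adjusted p = 5.21e-20 and 2.63e-10), with adjusted p = 0.36 and 0.41 with an estimated correlation.

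Among genes of fluoropyrimidine and thymidylate metabolism, 22 of 28 fell and 2 rose, at a median of -1.13 (camera adjusted p = 4.02e-07, and adjusted p = 0.36 with an estimated correlation). The ribonucleotide reductase subunit RRM1 (-3.08, SE 0.23), the folate enzyme SHMT1 (-2.16, SE 0.14), the uracil glycosylase UNG (-1.90, SE 0.15) and the uridine kinase UCK2 (-1.45, SE 0.11) fell. Thymidylate synthase, TYMS, named here after its value was seen because it is the target of the drug, fell from 66.9 ± 20.4 to 11.05 ± 3.03 CPM (-2.60, SE 0.25, edgeR adjusted p = 5.78e-06). The uridine phosphorylase UPP1, also named after its value was seen, rose.

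Target genes of p53 rose: 24 of 32 were higher, 2 were lower and 6 did not pass, at a median log2 fold change of 0.79. MDM2, the ubiquitin ligase that limits p53, rose from 128 ± 36.1 to 808 ± 127 CPM (2.66, SE 0.21), TP53INP1 rose by 2.60 (SE 0.16), PLK3 by 1.87 (SE 0.17) and SUSD6 by 1.28 (SE 0.13) on the log2 scale. The 2 that fell, CCNG1 (-1.26) and CMBL (-0.68), were named after their values were seen. The list passed camera (adjusted p = 2.42e-05), with adjusted p = 0.41 with an estimated correlation.

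Genes of protein synthesis fell. All 58 ribosomal protein genes were lower, at a median of -1.87, and their share of counts went from 4.78% ± 0.11 to 1.40% ± 0.35 (SD, n = 3 per group; exact two-sided permutation p = 0.1, the smallest 3 against 3 can give). RPL10A (-2.52), RPL3 (-2.49), RPL12 (-2.72) and RPL4 (-2.34) had the smallest p. Of 37 ribosome biogenesis genes 33 fell and 1 rose, with the nucleolar proteins FBL (-3.29), NPM1 (-2.59), NPM3 (-2.06) and LYAR (-1.78). Both lists passed camera (adjusted p = 9.45e-27 and 2.26e-09), with adjusted p = 0.36 and 0.42 with an estimated correlation. Ribosomal protein genes have many processed pseudogenes that can share their reads. The share of mitochondrially encoded transcripts rose in the same libraries.

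Mitochondrially encoded transcripts took 4.80% ± 0.12 of counts in control and 26.7% ± 1.59 in 5-FU libraries (SD, n = 3 per group; exact two-sided permutation p = 0.1). All 13 mitochondrial mRNAs rose, at a median of 2.26 (camera adjusted p = 1.25e-19, and adjusted p = 0.087 with an estimated correlation), and the most abundant, MT-CO1, a subunit of cytochrome c oxidase, went from 13385 ± 767 to 77162 ± 5655 CPM. The 10 most counted genes took 5.73% of counts in control and 23.9% in 5-FU libraries.

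**Figure D2:**
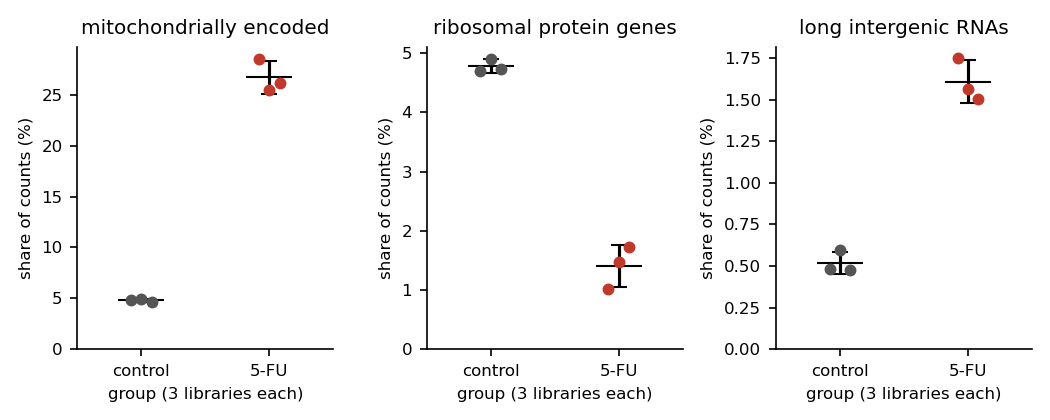
Share of all counts, in percent, taken by mitochondrially encoded genes, ribosomal protein genes and long intergenic RNAs in each of 3 control (grey) and 3 5-FU (red) libraries, with mean and SD. The mitochondrial share is 25.5% to 28.5% after 5-FU against 4.66% to 4.88% in control.

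Metabolic lists fell, though the call of hypoxia and glycolysis was not kept in every setting. Cholesterol synthesis genes were lower for 24 of 25 members and higher for 1, at a median of -1.34, with INSIG1 (-2.93), FDFT1 (-1.87) and NSDHL (-1.61). NRF2 target genes, of the oxidative stress response, fell for 17 of 27 and rose for 4, with NQO1 (-2.28), PGD (-1.83), UGDH (-1.77) and TALDO1 (-1.38). Genes of hypoxia and glycolysis fell for 16 of 31 and rose for 5; LDHA (-2.45), TPI1 (-1.94), GPI (-1.62) and PKM (-1.53), enzymes of glycolysis, were among those that fell. Genes of the unfolded protein and amino acid stress response fell for 19 of 29 and rose for 2: SHMT2 (-2.32), PHGDH (-2.70) and SDF2L1 (-2.04) fell, while the stress-induced factor ATF3 rose (3.00, SE 0.23). The camera adjusted p was 7.98e-08, 0.0021, 0.036 and 0.0058 for these 4 lists in the order given, and adjusted p = 0.36, 0.56, 0.63 and 0.63 with an estimated correlation. Camera sets a list against all tested genes. Of the 3954 genes in the quintile with the highest mean expression, 2388 fell and 703 rose. Whether these 4 lists fell more than genes of like abundance was not tested. Of the other called lists, only the ribosomal protein genes were set against genes of like abundance, as described below. The call of the hypoxia and glycolysis list was lost at a mean count of at least 50 (median -0.37, camera adjusted p = 0.24), without 5-FU replicate 2 (adjusted p = 0.084), on the FPKM table (0.13) and with the length and GC trend removed (0.073).

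Most of the ETS family did not rise with ELF3. Of 21 tested ETS transcription factors 15 fell and 2 rose, with ETS2 (-1.42), ELK1 (-1.29) and ETV4 (-1.03) lower, at a median of -0.69 (camera adjusted p = 0.038, and adjusted p = 0.41 with an estimated correlation). The call was lost with upper-quartile factors (median -0.33, camera adjusted p = 0.066), at a mean count of at least 50 (-0.35, adjusted p = 0.40), without 5-FU replicate 1 (adjusted p = 0.052) and on the FPKM table (adjusted p = 0.051). Wnt target genes fell for 12 of 23 and rose for 4: NOTUM (-2.06), APCDD1 (-2.15) and MYC (-1.64) fell, and the Wnt inhibitor DKK1 rose (4.27, SE 0.51), at a median of -0.46 (camera adjusted p = 0.036, and adjusted p = 0.36 with an estimated correlation). Their call was lost at a mean count of at least 50 (median -0.28, camera adjusted p = 0.14) and on the FPKM table (-0.69, adjusted p = 0.051). Genes of NF-kB and inflammation fell for 13 of 27 and rose for 2; over the list alone 1 rose. LTB (-2.66), NFKB1 (-1.64) and NFKBIA (-1.29) fell and TRAF1 rose (2.25), at a median of -0.76 (camera adjusted p = 0.047, and adjusted p = 0.65 with an estimated correlation). That median was -0.39 without 5-FU replicate 1 and -0.49 without control replicate 1, and the call was lost in both (camera adjusted p = 0.086 and 0.064), as it was at a mean count of at least 50 (adjusted p = 0.18), on the FPKM table (0.12), in fry (0.057) and with the length and GC trend removed (0.065).

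Drug efflux transporters rose for 12 of 17 members and fell for 1, at a median of 0.68 (camera adjusted p = 0.037, and adjusted p = 0.55 with an estimated correlation; 0.060 without control replicate 1). ABCB1, the multidrug transporter P-glycoprotein, went from 320.0 ± 12.2 to 616 ± 99.4 CPM (0.95, SE 0.15), and ABCC10 (1.06), ABCC5 (0.93) and the little-expressed ABCC11 (2.20) rose. Mesenchymal transition genes rose for 6 of 15 and fell for 2, with CYR61 (3.76, SE 0.37), CTGF (3.63, SE 0.33) and TGFBI (0.95, SE 0.15) higher, at a median of 0.54 (camera adjusted p = 0.0488, and adjusted p = 0.36 with an estimated correlation). On the FPKM table the median of this list was -0.04 and its call was lost (camera adjusted p = 0.17), as it was with upper-quartile factors (median 0.89, adjusted p = 0.068), without the low-count filter (0.29, adjusted p = 0.060), at a mean count of at least 50 (adjusted p = 0.0501), in limma-voom (0.105), without 5-FU replicate 2 (0.053), with plain library totals (0.053) and with the length and GC trend removed (0.14). Histone genes that depend on replication rose for 5 of 11 and fell for 1, with HIST1H2AC (2.45), HIST1H4H (3.32) and HIST1H2BD (2.28) higher and HIST2H2AC lower (-3.16); all had a mean count under 200, and near-identical copies make them uncertain (median 0.91, camera adjusted p = 0.037, and adjusted p = 0.36 with an estimated correlation). Their call was lost with upper-quartile factors (camera adjusted p = 0.066), without the low-count filter (0.091), in limma-voom (0.065), without control replicate 2 (0.051) and with the length and GC trend removed (median 0.26, adjusted p = 0.23). Only 11 of 25 matched histone genes had enough counts to be tested. HIST1H4C, for example, had 1, 1 and 2 counts in control and 1, 1 and 4 in 5-FU libraries. The tested members therefore do not show how replication-dependent histone mRNA as a whole changed.

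Stem cell markers went both ways. CD44 belongs to this list, of which 6 of 18 tested members rose and 8 fell (camera adjusted p = 0.44; median -0.32, mean 0.07, camera direction down); in fry, which does not set a list against other genes, it passed with direction down (adjusted p = 0.0147). MYC fell, while DCLK1 (3.62, SE 0.36) and CD24 (4.67, SE 0.55) rose from under 1 CPM; CD24 has near-identical pseudogenes and its value is uncertain. Intestinal differentiation markers rose for 8 of 19 and fell for 5 (median -0.27, mean 0.31, camera direction up, adjusted p = 0.73), with CDHR5 higher (2.16) and LGALS4 (-2.11) and CDX2 (-1.14) lower. Epithelial genes rose for 5 of 27 and fell for 12 (camera adjusted p = 0.49); the laminin chains LAMB3 (2.33) and LAMA3 (1.37) rose and PKP2 fell (-0.82).

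Interferon stimulated genes rose for 7 of 35 and fell for 15 (camera adjusted p = 0.49), with TRIM22 (4.66) and STAT2 (1.53) higher and DTX3L lower (-1.52). Immediate early genes rose for 11 of 26 and fell for 8 (median -0.12, mean 0.37, camera direction up, adjusted p = 0.30); ATF3, FOSB (2.82) and DUSP1 (2.01) rose. Apoptosis regulators rose for 8 of 31 and fell for 12 (camera adjusted p = 0.44; 11 fell over the list alone), with BID (-1.70) and FADD (-1.98) lower; exons of an antisense gene cover 54.9% of FADD. Heat shock genes rose for 3 of 14 and fell for 7 (median -0.65, camera adjusted p = 0.13), with HSPD1 (-2.18), HSPE1 (-1.90) and HSP90AB1 (-1.65) lower. This list passed without control replicate 2 (median -0.82, camera adjusted p = 0.0057) and without the low-count filter (-0.80, adjusted p = 0.0048), and without that filter the lists of epithelial, interferon stimulated and apoptosis genes passed too, each with direction down (adjusted p = 0.046, 0.046 and 0.035).

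Markers of other cell types were few. Of 5 tested fibroblast markers 3 rose and 1 fell (camera adjusted p = 0.18), and the most abundant, COL1A1, went from 15.2 ± 3.06 to 42.4 ± 16.1 CPM. Of 6 leukocyte markers 1 fell (camera adjusted p = 0.65; median 0.03, mean -0.07), the most abundant being CORO1A at 15.1 ± 2.10 and 3.49 ± 0.66 CPM. Of 4 endothelial markers, too few for camera, 1 rose and 1 fell, and the most abundant, ESAM, was at 5.99 ± 0.87 and 7.89 ± 1.06 CPM (edgeR adjusted p = 0.083). Of 5 markers of other epithelial lineages 3 rose (camera adjusted p = 0.037, and adjusted p = 0.36 with an estimated correlation), the most abundant being KRT15, from 3.89 ± 1.14 to 30.2 ± 6.09 CPM; this call was lost in limma-voom (camera adjusted p = 0.055) and without control replicate 2 (0.050). Adjusted over the list alone, each list gave the counts stated above except where another is named.

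**Figure D3:**
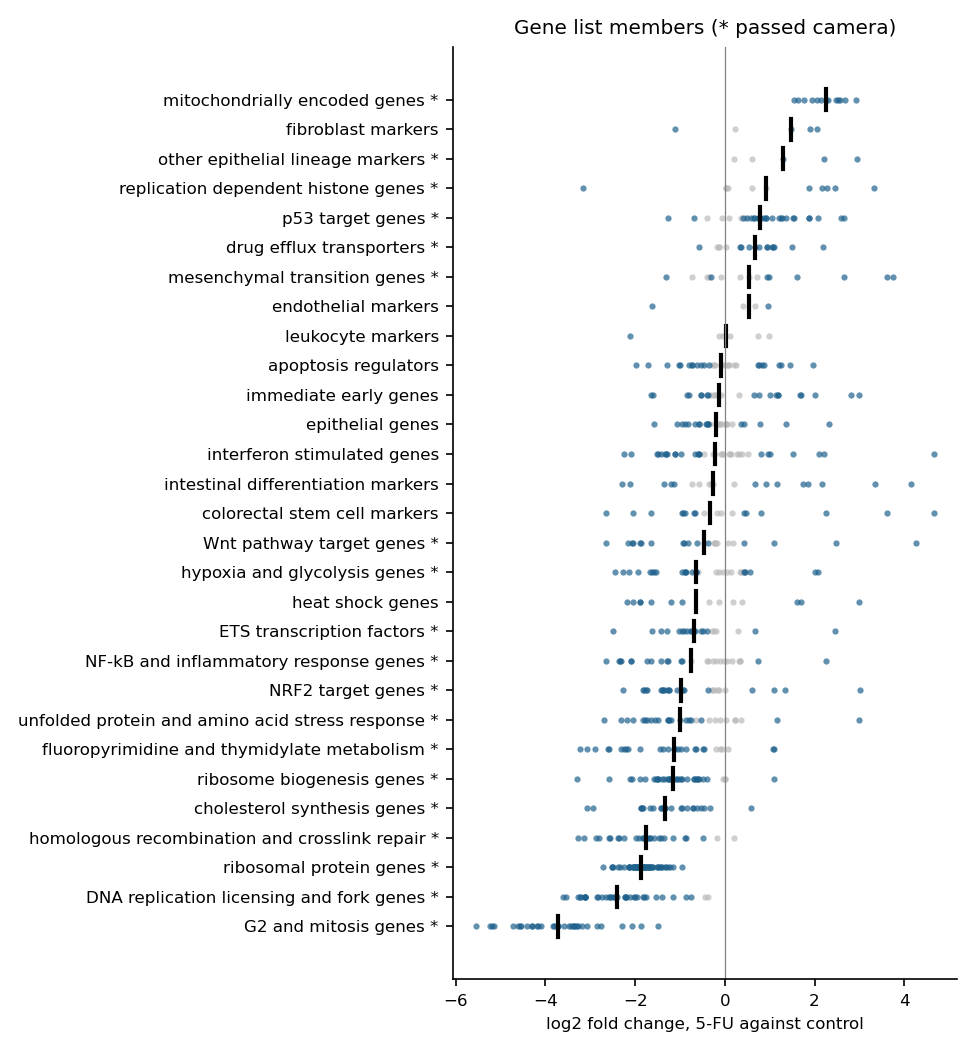
Log2 fold change (5-FU against control, 3 libraries each) of each tested member of the 29 gene lists; blue points passed the gene test, grey points did not, black bars are medians, and an asterisk marks a list with a camera adjusted p under 0.05 at the preset correlation. G2 and mitosis genes lie furthest to the left (median -3.72) and mitochondrially encoded genes furthest to the right (median 2.26).

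Direction went with abundance and gene class. In the expression quintile with the lowest means, 2294 genes rose and 197 fell, while in the quintile with the highest means 703 rose and 2388 fell. Among protein-coding genes 3947 rose and 6182 fell; among long intergenic RNAs 670 rose and 78 fell, among antisense RNAs 1033 and 92, and among sense-intronic RNAs 195 and 3. Genes with at least 1 count numbered 28382 ± 672 in control and 33287 ± 472 in 5-FU libraries (SD, n = 3 per group; exact two-sided permutation p = 0.1).

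**Figure D4:**
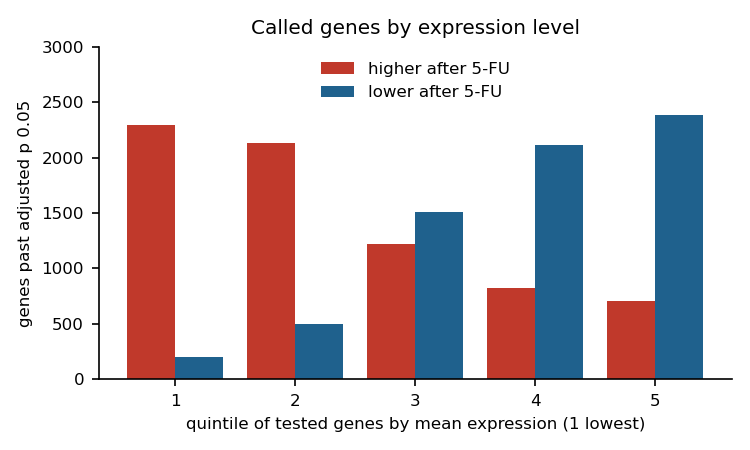
Number of genes higher (red) and lower (blue) after 5-FU at an edgeR adjusted p under 0.05 in each quintile of the tested genes, ordered by mean expression over the 6 libraries. Of the calls in the lowest quintile 92.1% are increases, against 22.7% in the highest.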

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

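Plain library totals, leaving out mitochondrial genes and removal of the length and GC trend were chosen after seeing the data; the other settings were not. The ELF3 increase passed in each of the 19 alternatives, with a log2 fold change of 2.16 to 2.83. The CD44 increase kept its sign in all of them but lost its call in 6: without the low-count filter (0.28, edgeR adjusted p = 0.111), in DESeq2 (0.28, adjusted p = 0.109), on the FPKM table with a pseudocount of 1 (0.24, limma adjusted p = 0.0791) or 0.1 (0.28, adjusted p = 0.0799), on that table without a filter (0.24, adjusted p = 0.12), and without control replicate 3 (0.33, edgeR adjusted p = 0.0758). Over the 6 fits that leave out 1 library the CD44 log2 fold change was 0.33 to 0.50 and that of ELF3 2.32 to 2.63. CD44 stood 0.34 above the median of all genes with TMM, DESeq2 size factors, upper-quartile factors or plain totals, 0.66 above it at a mean count of at least 50, and 0.35 below it (-0.35) without the filter, where the median of all genes tested is 0.63. Its place among all genes thus depends on the filter, as 39721 genes were tested without it and 19771 with it. The log2 fold changes of CD44 and ELF3 shifted alike, from 0.43 and 2.47 to 0.28 and 2.32 without the filter. At a mean count of at least 50 they were 0.68 and 2.72. A shift shared by genes is what a change of library scaling gives. TMM factors were computed anew on the genes that each filter kept, so a change of filter changed the scaling too. With the filter unchanged, upper-quartile factors also moved both genes alike, to 0.79 and 2.83.

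The count of changed genes was 13060 to 14104 over the fits that leave out 1 library. It was 8214 at a fold change of at least 2, with 3206 lower, where the stricter threshold itself removes genes. The number of higher genes was 4320 on the FPKM table with a pseudocount of 1, 4268 with 0.1 and 3953 among protein-coding genes alone. These settings test fewer genes of low abundance, at a scaling that was not computed anew for them. At a mean count of at least 50, with TMM factors computed anew, 5141 genes were higher and 4935 lower. The DESeq2 test called 13713 genes. Of the main calls, 98.5% remained in the same direction with DESeq2 size factors and 84.9% with upper-quartile factors. The replicate numbers gave no sign of pairing: deviations of same-numbered libraries correlated at -0.07, -0.20 and 0.06 across genes, which are not independent replicates. Differently numbered control and 5-FU libraries correlated at -0.12 to 0.17. With so few libraries these values cannot exclude pairing. With the replicate number as a block 13243 genes and 19 lists were called, and the CD44 log2 fold change was 0.43.

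Of the 19 called lists none passed with an estimated correlation (0 lists), and 11 kept their call in all other settings. The remaining lists, named above, each lost it in at least 1. Calls were gained by 4 lists without the low-count filter, 1 of them also without control replicate 2, as reported above, and in fry by stem cell, immediate early, fibroblast and leukocyte genes (adjusted p = 0.0147, 0.0486, 0.0033 and 0.0367). Lists called numbered 17 to 19 without 1 library, 13 at a mean count of at least 50 and 22 with fry. Direction turned for 4 lists that passed in neither setting: at a mean count of at least 50 the medians of epithelial, interferon stimulated and apoptosis genes were 0.053, 0.10 and 0.10, and on the FPKM table the camera direction of intestinal differentiation markers was down (median -0.47); the cause was not tested. Of 2098 values of the other 111 named genes, 2094 kept direction and side. ESAM passed in 3 settings and MT-CO1 did not pass on the unfiltered FPKM table (2.38, limma adjusted p = 0.768). The mitochondrial share rose by 19.3 percentage points for mRNAs alone against 21.9 for all its genes.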

Other observations

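All lists and tests of this part were chosen after the results were seen, except the test of nuclear-encoded respiratory chain genes and the count of other splits. Target genes of YAP and TEAD, which respond to cell shape and tension, rose for 15 of 22 tested members and fell for 1, at a median log2 fold change of 0.51 (camera adjusted p = 0.0030, and adjusted p = 0.48 with an estimated correlation). The list was written after ANKRD1 had been seen among the largest increases and holds CYR61 and CTGF, which stand in the mesenchymal list too. The 17 members in no earlier list and not yet named had a median of 0.49, with 11 higher and 1 lower (camera adjusted p = 0.075 over 6 lists, which does not pass). AMOTL1 (4.77, SE 0.46) and NUAK2 (0.90, SE 0.13) were higher and FJX1 was lower (-1.12, SE 0.22). YAP activity may be raised in the treated cells; this is a hypothesis, and no direct readout of YAP was measured.

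Long non-coding RNAs known to stay in the nucleus rose for 6 of 7 tested members, at a median of 1.86 (camera adjusted p = 3.20e-05, and adjusted p = 0.13 with an estimated correlation). MALAT1 went from 347 ± 23.8 to 4014 ± 1077 CPM and NEAT1 from 799 ± 252 to 4898 ± 377 CPM (SD, n = 3 per group), while TUG1 was at 213 ± 3.00 and 220.0 ± 9.62 CPM (edgeR adjusted p = 0.72). Long intergenic RNAs as a class rose for 670 of 1242 and fell for 78 (median 0.91), and a rise particular to nuclear RNAs was not tested. Lysosome genes rose for 8 of 37 and fell for 11 (median -0.017, camera adjusted p = 0.85; with upper-quartile factors the median was 0.34). Genes of C2H2 zinc finger proteins rose for 166 of 475 and fell for 127 (median 0.086, camera adjusted p = 0.42; with upper-quartile factors the median was 0.445). Of 10000 lists matched on length and expression, whose median was -0.025, 3.21% reached 0.086. Members of both lists went both ways and neither list passed camera, so whether either moved as a group stays open.

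The rise in mitochondrial transcripts was weighed against 3 explanations. A single loss of nuclear RNA would raise each mitochondrial mRNA by 1 factor, but their log2 fold changes ran from 1.55 for MT-ATP8 to 2.93 for MT-ND1, a range of 7.33 times their median SE, which argues against it as the whole cause. A general rise of respiratory chain transcripts is argued against by the nuclear-encoded subunits, of which 48 of 52 fell (median -1.25, camera adjusted p = 2.32e-14, and adjusted p = 0.34 with an estimated correlation). Less complete selection of polyadenylated RNA stays open: of 3 tested RNA polymerase III transcripts 2 fell and 1 rose (median -1.80), whereas 25 of 32 small nuclear RNAs and both mitochondrial ribosomal RNAs rose. A change in mitochondrial transcription or RNA decay under 5-FU is open too and was not tested.

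The detection of more low-abundance genes after 5-FU was weighed against 2 explanations. Depth is argued against: the 5-FU libraries hold fewer counts, and with each library thinned to 18459939 counts the lowest 5-FU library still listed 4102 more genes than the highest control library. Genomic DNA stays open for these detections. Counts of 373 olfactory receptor genes, below the count filter in these data and taken as silent, rose from 205 to 513 summed over 3 libraries. Their gain per kilobase, given to every gene, would bring a count to 3558 further genes in a control library (mean of 3), against the 4905 seen. The 894 sense-intronic genes gained 0.60 CPM per kilobase, pooled, against 0.0062 for the olfactory receptor genes. Of these 894 genes, the 277 that passed the count filter held 50930 of their 55767 counts in the 5-FU libraries. The olfactory receptor genes were limited to those below it, so the sets were chosen unlike, which can widen the contrast. Over all 894 genes the median gain was 0.147 CPM per kilobase. These gains argue against DNA at the olfactory rate as the whole cause of the sense-intronic rise, though the size of the contrast is uncertain. A larger share of unspliced or nuclear RNA is a candidate explanation that gene-level tables cannot test.

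The fall of ribosomal protein transcripts was weighed against 3 explanations. With the trend on length and GC removed, their median still stood 1.87 below that of all genes (difference -1.867, camera adjusted p = 2.74e-15). Counts did not move to pseudogenes, whose summed CPM fell as well, from 2697 ± 30.9 to 896 ± 161 (SD, n = 3 per group; log2 ratio -1.59). Of 10000 lists matched on length and expression 0% had a median as low, though the matched lists fell to a median of -1.25 themselves and were somewhat less abundant. Matched genes were drawn independently, so the spread of these medians does not allow for ribosomal protein genes that move together. The 0% is therefore not a p-value. Part of the fall is thus shared with genes of like length and abundance. Length is that of all exons of a gene, with medians of 3460 bases for ribosomal protein genes and 3549 for matched genes. The length of single transcripts was not tested. These results argue against length and GC content and against pseudogenes as the whole cause. They argue less firmly against a fall shared by genes of like length and abundance. Lower levels of ribosomal protein mRNA after 5-FU remain a hypothesis found and tested on the same data.

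Of the 10 ways to split the 6 libraries into 3 and 3, only the real split, 1 of 10, gave as many genes as the 13877 called by edgeR. The highest of the others gave 0 genes, 179 at an unadjusted p under 0.05, 0 with limma-voom and 1 with DESeq2. Each of the other splits puts control and treated libraries on both sides. The difference between the groups then adds to the spread within each side, which lowers the number of calls. These low counts are therefore not the level that chance alone would give. With 10 splits the share cannot go below 0.1, which is too few to decide on chance.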
